A study of Homo sapiens with 9 samples.

How the data were processed

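The series holds 9 arrays of RNA from SH-SY5Y cells, 3 untreated, 3 exposed to a-synuclein oligomers and 3 exposed to rotenone, and each array's group and replicate number were taken from its title. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was removed, and the rest was amplified with random primers along the whole transcript into fluorescent cRNA and hybridised to the Arraystar Human LncRNA Microarray V4.0 by Agilent's single-colour protocol. Per the submitters' processing notes and the file headers, the images were read with Agilent Feature Extraction 11.0.1.1, and the files' design was annotated to the hg19 build. Exposure times are not given in the sources used here.

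The deposited files hold spot intensity on a linear scale, not normalized between arrays: per the file headers, the processed signal is Feature Extraction's intensity after background subtraction and detrending, and the raw median spot and local background intensities stand beside it with flags for outliers, saturation and signal well above background. The processed signal has a floor above 0, so values near the floor have no order. The flags come from the authors' scanner software.

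Each array held 61464 non-control spots, of which 360 were negative controls (60 sequences) and were set aside. The rest were 60904 Arraystar probes and 20 probes with RefSeq accessions, each printed 10 times. Spots marked as non-uniformity or population outliers were left out (9 to 25 on control and oligomer arrays, 32 to 133 on rotenone arrays), and spots of a probe were averaged on the log2 scale. The processed signal was turned to log2 and each array's 75th percentile over all non-control probes was subtracted. A probe was well above background on an array if over 50% of its spots carried the flag, and probes so marked on at least 3 of the 9 arrays (33740) were tested; 24077 were so on all 9. Array intensity sets the precision here, and the rotenone arrays had a smaller share of probes well above background than the others.

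Linear models with moderated variances were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 over all 9 arrays with group as the only factor, and the 3 pairwise differences were tested two-sided with Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. Standard errors are limma's moderated ones. Single values per array were compared by exact permutation of the 3 against 3 arrays. Files were read with jsonlite 2.0.0 and the data.table package (version 1.17.8), and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The steps were tested on simulated data for 33574 probes, with known changes of 4 sizes in 50 probes each. For oligomers against control, 66% of rises of 1 and 90% of rises of 2 on the log2 scale were recovered, 46% of changes of −1 and 4% of rises of 0.5, with 2 false calls. For rotenone against control the shares were 60%, 88%, 50% and 0%, with 8 false calls. Only the probes with known changes differed between the simulated groups, and no array was dimmed. With so few changes the adjustment is stricter than in the real rotenone fit, so these shares do not describe that fit.

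Gene symbols came only from the 20 accessions, all of which (20) matched the RefSeq gene table supplied for assembly GRCh38.p14; because the build differs from hg19, no coordinates are given. Results are given for 18 of these genes, and the others are not reported here. The Arraystar probes have identifiers only in the tables used here, so at most 2 that rose and 2 that fell are named per comparison. The rule set before the data were examined named up to 10 rises and 10 falls per comparison among genes with a symbol that passed, were above background on all arrays compared and moved the same way in each treated array, genes below background in a group as a bound, the 5 smallest p where none passed, and members of fixed lists. It also named, among others, TH, SLC6A3, NQO1, HMOX1, DDIT3, ATF4 and CDKN1A, which none of the 20 symbols covers, and GAPDH. The 43 gene lists fixed at the same time could not be tested as sets, since 0 had at least 5 tested genes and the largest had 2; 3 lists had any gene reported here, and those genes are given singly. GAPDH and PGK1 also have 3′ and 5′ control spots, which were kept apart from the tested probes.

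The slide and scan time in the file headers gave 2 batches, with 7 arrays in scan 1 and 2 in scan 2, so each comparison was also fitted with the scan as a block and within scan 1; scan 2 holds 1 array of each of 2 groups, which gives no test of its own. Within groups, arrays correlated with r from 0.979 to 0.994 over tested probes, and none were identical. Alternatives tried were quantile normalization, normexp background correction (offset 50), a median shift, other filters on dim probes, flagged spots kept, fits of only the groups compared, the replicate number as a block, an intensity trend with robust variances, array weights, fold thresholds and leaving out each array. Chosen after seeing the data were normexp on the median in place of the mean signal (which the files used here do not hold), a percentile over probes detected on all 9 arrays, no scaling, and scan 1 alone.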

Results

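Gene expression was measured on 9 single-colour microarrays carrying 60924 distinct probes for human long non-coding and messenger RNAs, hybridised with RNA of the neuroblastoma line SH-SY5Y, which the labels spell SY-SH5Y. The line grows from neural crest tumour cells and is widely used as a stand-in for dopaminergic neurons. Cells were left untreated (3 arrays), exposed to oligomers of a-synuclein, the protein that aggregates in Lewy bodies (3 arrays), or exposed to rotenone, an inhibitor of mitochondrial complex I (3 arrays). The design text gives the doses as 25 mmol/L of oligomers and 10 mmol/L of rotenone, and those units are repeated here as written. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision.

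The rotenone arrays were dimmer than the others before any scaling. The 75th percentile of the probe signal was 117.2 ± 7.28 (SD, n = 3) in control, 116.2 ± 4.09 with oligomers and 63.0 ± 3.49 with rotenone, a rotenone level 0.538 times that of control. The two-sided exact permutation p was 0.1 for rotenone and 1 for the oligomers, where 0.1 is the smallest value that 3 arrays against 3 allow. The share of probes well above background was 55.8% ± 1.73 in control, 52.6% ± 1.19 with oligomers and 45.1% ± 1.25 with rotenone (exact p = 0.1 for each treatment). The raw signal of the negative control spots was 60.7 ± 2.52, 63.7 ± 4.16 and 63.8 ± 2.36 in the same order, and no spot was saturated (0 on each array). The arrays were read in 2 scans, each of a slide of its own, with 7 arrays in scan 1 and 2 arrays (1 oligomer, 1 rotenone) in scan 2. Within scan 1 the rotenone arrays lay −0.875 (log2) from control, and in scan 2 the rotenone array lay −0.87 from the oligomer array, beside −0.895 from control over all arrays. On the slide of scan 1 all controls sat in row 1 and all treated arrays in row 2, and within row 2 rotenone lay −0.89 from the oligomer arrays.

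**Figure D1:**
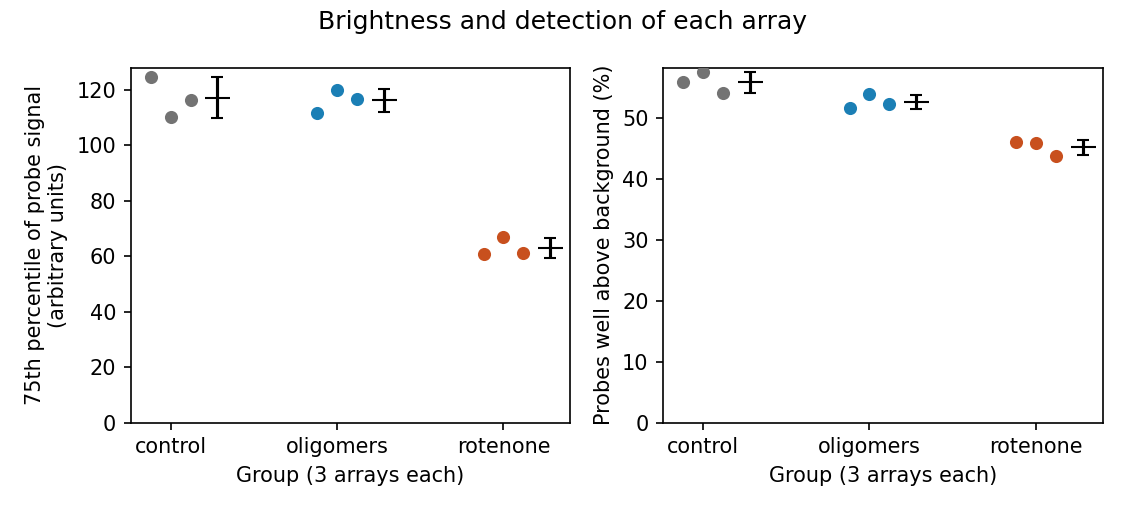
Left, the 75th percentile of the probe signal (arbitrary units) and right, the percentage of probes well above background, for each of the 9 arrays (points), with the mean and SD of the 3 arrays of a group beside them. The rotenone arrays lie between 60.8 and 67.0 in signal, below the 110.3 to 124.8 of the control arrays.

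The comparison of rotenone with control asks what a toxin model of Parkinson's disease does to the cells' transcripts. Scaled to each array's 75th percentile, 13996 of 33731 tested probes (41.5%) differed in limma's test at an adjusted p under 0.05, of which 6788 were higher and 7208 lower with rotenone. At least 2-fold changes made up 4539 of these, 2453 higher and 2086 lower. Probe ASHGV40018996 rose from a signal of 3663 ± 1630 to 207900 ± 6200, a log2 change of 6.82 ± 0.315 (SE, n = 3 against 3, adjusted p = 7.11e-06), and ASHGV40055426 rose by 6.31 ± 0.418 (adjusted p = 1.88e-05). In the other direction, ASHGV40005130 went from 9343 ± 220 to 67.1 ± 24.1, a change of −6.30 ± 0.263 (adjusted p = 5.21e-06), and ASHGV40017872 changed by −5.64 ± 0.149 (adjusted p = 5.96e-07). These 4 kept their direction and their call under all 6 scalings tried, and no table used here pairs their identifiers with a gene. Of probes well above background on all 3 control arrays, 2752 were so on no rotenone array, against 77 the other way round. These detection counts are not scaled, so the lower brightness of the rotenone arrays enters them.

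Results are given for 18 probes with a gene symbol, of which 15 were bright enough to be tested, and among these 7 rose and 4 fell with rotenone, each in 3 of 3 rotenone arrays. RPS18, a protein of the small ribosomal subunit, rose the most (log2 change 1.05 ± 0.119, SE, adjusted p = 1.9e-04), followed by PRMT1, the main enzyme of asymmetric arginine dimethylation (0.91 ± 0.0982, adjusted p = 1.44e-04). Both stayed above 0 under all 6 scalings, but RPS18 was not past the threshold without scaling (0.15), nor PRMT1 without scaling (0.015) or under quantile normalization (0.24). ODC1, the enzyme that starts polyamine synthesis, rose by 0.81 ± 0.102 (adjusted p = 3.17e-04), but lay at −0.081 without scaling and, at 0.35, was not past the threshold under quantile normalization. The ribosomal stalk protein RPLP1 (0.70 ± 0.0943), the cytoskeletal actin ACTB (0.52 ± 0.0934) and the histone gene H3-3A (0.43 ± 0.0977) rose in the main scaling and turned negative under quantile normalization (−0.19, −0.28 and −0.18) and without scaling (−0.20, −0.38 and −0.46).

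Among the tested genes with a symbol, fewer fell than rose in the main scaling. PFN1, the actin-binding protein profilin, fell (−0.37 ± 0.116, adjusted p = 0.0301), and so did MTX1, a protein of the mitochondrial import machinery (−0.33 ± 0.0981, adjusted p = 0.0253), and both kept their sign under all 6 scalings. The probe for EIF3D, a subunit of the translation initiation factor that binds the small ribosomal subunit, fell (−0.58 ± 0.113, adjusted p = 0.00317). Its signal went from 51.0 ± 7.92 to 18.2 ± 2.62, with 2 of the 3 rotenone arrays well above background. After normexp background correction with the percentile the change lay at 0.028. The offset of 50 used with normexp is near this probe's control signal and shrinks log2 changes of dim probes by construction. In the other 5 scalings, normexp with quantile normalization among them, EIF3D stayed lower and called. The probe for PGK1, a glycolytic kinase, had a signal of 47.2 ± 2.57 in control and was not well above background on any rotenone array, which makes the probe at least 1.44-fold lower (adjusted p = 0.00218). Its change was −0.0078 after normexp with the percentile, while in 5 of 6 scalings the fall of the probe was called. Control spots for the same gene rose, so a fall of the gene is not established. Such bounds set the bright group's mean against, per array, the higher of the lowest signal well above background and the probe's own signal.

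By the lists fixed beforehand, 2 of 22 glycolysis genes were measured. The GAPDH probe rose (0.33 ± 0.0967, adjusted p = 0.0244), the PGK1 probe fell, and both passed over all probes and both when adjusted over the list alone. GAPDH turned to −0.37 under quantile normalization, −0.043 after normexp with the percentile and −0.57 without scaling. Separate control spots for the 3′ and 5′ parts of these transcripts did not all follow the probes. Scaled likewise, the GAPDH spots changed by 0.17 at the 3′ end and −0.64 at the 5′ end, and the PGK1 spots by 0.51 and 0.39, against the direction of the PGK1 probe. The 3′ PGK1 spots were bright, at 48730 ± 1940 in control and 37400 ± 1310 with rotenone before scaling. Of the 50 genes on the list of cytosolic ribosomal proteins, which leaves out RPS18, 2 were measured. RPLP1 rose, over all probes and adjusted over the list alone, while the RPL10 probe was not well above background on any array. The probe for COX4I1, of the list for respiratory complexes III to V, was not well above background on any array either. A dim probe does not show that its transcript was absent, since the PGK1 probe was dim where the 3′ PGK1 spots were bright. ARHGDIA (−0.023 ± 0.0965) and DYNLL1 (−0.20 ± 0.146) did not pass. Neither did ACTG1 and GRM4, which were not well above background on any rotenone array.

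The direction of the rotenone changes is relative to the array's brightness. Without scaling the median change of all tested probes was −0.93 and 26498 probes were called, 1494 higher and 25004 lower. In the brightest decile of probes, where the genes that rose lay, the median change before scaling was −0.59. That loss was smaller than the −0.895 that the main scaling takes out, so the main scaling moved this decile up as a group. A median shift called 14542 (5337 higher, 9205 lower), and normexp before the percentile called 22472 (14285 higher, 8187 lower). With the scan as a block 14462 probes were called and within scan 1 alone 13560, where 11 and 10 of the 11 gene calls held, GAPDH being the loss (adjusted p = 0.0822). The calls of GAPDH, MTX1 and PFN1 were close to the threshold and were lost on leaving out single arrays: GAPDH without control 1 or 3 or rotenone 1 or 3, MTX1 without control 1 or 3 or rotenone 1 or 2, and PFN1 without oligomer array 3, any control, or rotenone 1 or 2, with adjusted p up to 0.0907 in limma.

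**Figure D2:**
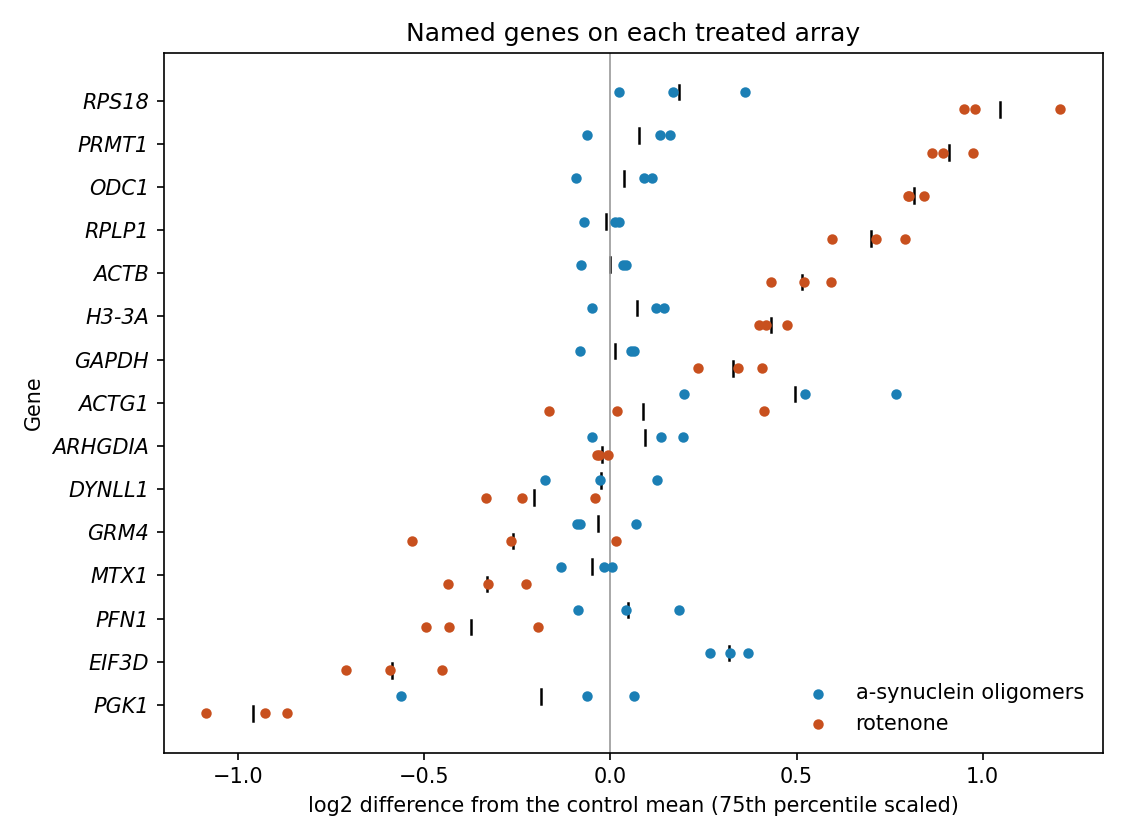
The log2 difference from the control mean, after scaling to the 75th percentile, of the 15 tested genes with a symbol on each oligomer array (blue) and each rotenone array (orange), with the mean of 3 arrays as a black bar. RPS18, PRMT1 and ODC1 lie highest with rotenone and PGK1 and EIF3D lowest. The rises of RPLP1, ACTB, H3-3A and GAPDH turn to falls under quantile normalization, that of ODC1 only without scaling. After normexp with the percentile EIF3D lies at 0.028 and GAPDH at −0.043. ACTG1, GRM4 and PGK1 were not well above background on any rotenone array.

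The comparison of a-synuclein oligomers with control asks what the oligomer model does on its own. No probe passed: 0 of 33740 had an adjusted p under 0.05 in limma, with the smallest at 0.121. At an unadjusted p under 0.05 there were 1274 probes (574 higher, 700 lower), where chance alone would give 1687. Named here are the 2 rises and 2 falls with the smallest p. They were picked among probes above background on all 6 arrays that moved the same way in 3 of 3 oligomer arrays. Each of the 4 had an adjusted p of 0.121 in limma. They were ASHGV40033663 (1.12 ± 0.133, SE; signal 1074 ± 24.4 in control and 2331 ± 344 with oligomers), ASHGV40036996 (0.86 ± 0.101), ASHGV40019151 (−0.95 ± 0.0907; 7394 ± 355 and 3785 ± 53) and ASHGV40019159 (−0.76 ± 0.0858). Of these, 3 passed under other scalings, ASHGV40019151 in 3 of 6 and ASHGV40033663 and ASHGV40019159 in 2 of 6 each. Of the genes with a symbol, the 5 with the smallest p did not pass either. EIF3D stood at 0.32 ± 0.113, ACTG1, a cytoskeletal actin, at 0.50 ± 0.182, RPS18 at 0.18 ± 0.119, PGK1 at −0.19 ± 0.172 and ARHGDIA at 0.09 ± 0.0965, each with an adjusted p of 1. The glycolysis and ribosomal lists had 0 calls over all probes and 0 adjusted over the list alone.

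The count of 0 was not fixed across settings. Weighting the arrays called 90 probes (53 higher, 37 lower). That fit rested mostly on 1 array of each group. Control array 3 had a weight of 5.41 beside 0.799 and 0.718, and oligomer array 3 had 2.93 beside 0.634 for each other oligomer array. Leaving out oligomer array 2 called 46 (40 higher, 6 lower), and the other settings at this threshold called 0 to 10. With the scan as a block and within scan 1 alone the count was 0. The spread of the changes was narrow, with an SD over probes of 0.237 (log2) against 0.76 for rotenone, and 9 probes gained and 243 lost detection on all 3 arrays.

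**Figure D3:**
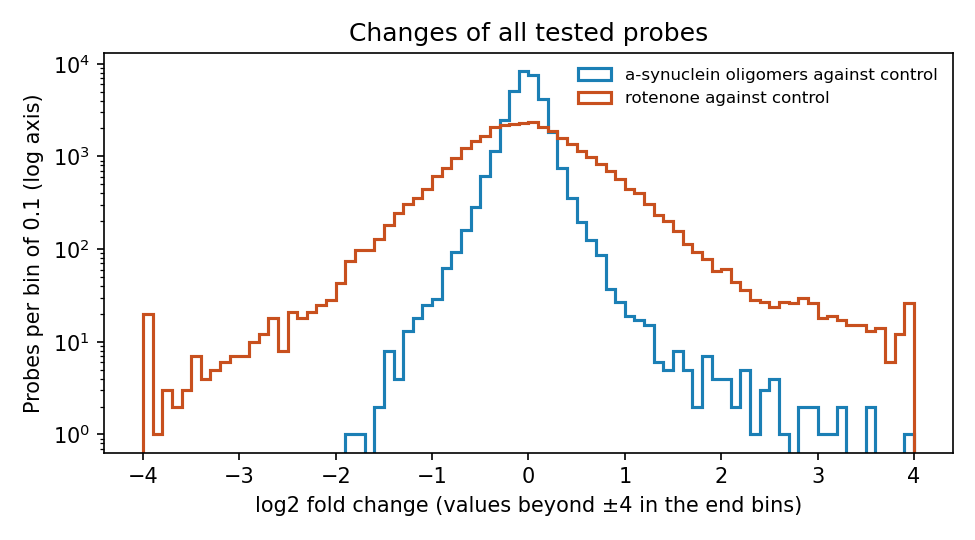
Histogram of log2 fold changes against control over all tested probes, in bins of 0.1 with a logarithmic count axis, for oligomers (blue) and rotenone (orange); values beyond 4 either way are in the end bins. The rotenone changes are wider (SD 0.76) than the oligomer changes (SD 0.237).

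The oligomer and rotenone arrays were compared directly, which also tests whether the 2 effects against the shared control differ. In limma 14700 of 33731 probes (43.6%) differed, 7403 higher and 7297 lower with oligomers than with rotenone, and 11 of the 15 genes passed. EIF3D was higher with oligomers by 0.90 ± 0.113 (SE, adjusted p = 2.74e-04), though by 0.13 and not past the threshold after normexp with the percentile, and PFN1 by 0.42 ± 0.116 (adjusted p = 0.0172), and the PGK1 probe was at least 1.27-fold higher (adjusted p = 0.00627). Its change turned to −0.048 after normexp with the percentile. Within scan 1 the PGK1 call was lost (adjusted p = 0.0557), and the 3′ PGK1 spots, at −0.025 with oligomers and 0.51 with rotenone against control, went the other way. RPS18 (−0.86 ± 0.119), PRMT1 (−0.83 ± 0.0982), ODC1 (−0.78 ± 0.102) and RPLP1 (−0.71 ± 0.0943) were lower with oligomers in the main scaling and lay at 0.022, 0.051, 0.11 and 0.17 without scaling, where 24085 probes were higher and 1758 lower. RPLP1 also turned to 0.19 under quantile normalization, with and without normexp. A median shift called 9812 higher and 5521 lower, and normexp before the percentile 8324 higher and 14409 lower. Probes ASHGV40045102 (7.19 ± 0.534) and ASHGV40005130 (6.77 ± 0.263) were higher with oligomers, and ASHGV40018996 (−8.33 ± 0.315) and ASHGV40055426 (−7.42 ± 0.418) lower, under all 6 scalings. With the scan as a block 15650 probes were called, with 11 of the 11 gene calls kept, and 12614 within scan 1, with 7 kept. Leaving out single arrays ended the calls of MTX1 (any array but rotenone 3), GAPDH (oligomer array 2 or 3, rotenone 1 or 3), PFN1 (oligomer array 1 or 3, rotenone 1 or 2) and H3-3A (oligomer array 2), with adjusted p up to 0.128 in limma.

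Of the probes higher with rotenone, 6788 against control and 7297 against oligomers, 6216 were in both sets, and of those lower, 7208 and 7403, 6464 were in both, with 0 in opposite directions. Independent sets would share 1468 and 1582, but both sets use the same rotenone arrays, and part of the excess may come from them. Across 33731 probes, which are not independent replicates, the oligomer and rotenone changes against control correlated with Pearson's r = −0.0313 and Spearman's rho = −0.0426. Simulated groups with no effect that shared the control arrays gave r = 0.498. An effect of rotenone alone pulls both r and the share of equal signs toward no agreement. Of these measures, only the covariance can therefore be set against the simulation, and only roughly. The covariance was −0.00563, below the simulated 0.0264 (0.025 to 0.0281 in 100 draws) by a difference of −0.032. The spread of the control arrays alone gives 0.0208, outside the range of the draws. That range is thus too narrow to serve as a limit, and the comparison cannot decide whether the responses oppose each other. Changes had the same sign in 49.1% of probes, against 66.6% simulated. The 3 control arrays are too few to be split in groups of at least 2. Without control array 2 the correlation was 0.133.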

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

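All tests in this part were chosen after the results were seen, except the direct contrast and the splits of the arrays. The clearest difference between the treatments was in the response itself. The change against control differed between oligomers and rotenone for 14700 probes in limma, tested as the direct contrast of the 2 groups. It differed for 11 genes with a symbol. On the log2 scale, oligomers minus rotenone, these were EIF3D (0.90), PGK1 (0.77, the fitted value of a probe below background with rotenone), PFN1 (0.42), MTX1 (0.28), GAPDH (−0.32), H3-3A (−0.36), ACTB (−0.52), RPLP1 (−0.71), ODC1 (−0.78), PRMT1 (−0.83) and RPS18 (−0.86), in the main scaling; MTX1, PFN1 and EIF3D kept their sign in all 6 other scalings, and their call in 4, 6 and 5 of them. It differed as well for probes ASHGV40045102 (7.19), ASHGV40005130 (6.77), ASHGV40018996 (−8.33) and ASHGV40055426 (−7.42). Only 10 splits of 6 arrays exist, too few for a share under 0.05. The real split gave 14700 probes and the highest other 0, 1 of 10 splits giving as many. For rotenone against control the real split gave 13996 and the highest other 0 (1 of 10). For oligomers against control the real split gave 0 and the highest other 1, so 10 of 10 gave as many.

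The rotenone arrays were dimmer, and the weighing starts there. Scan and array row are argued against: the log2 difference in 75th percentile signal stayed at −0.87 or further from 0 in each of 3 comparisons within a scan or row, against −0.895 over all arrays. Dimmer arrays alone, a change that depends only on a probe's brightness, are argued against as the source of the 13996 calls: after quantile normalization, which removes such a change, 13857 probes were called, 12758 of the 13996 in the same direction and 9 in the opposite one, and in the brightest decile of probes the rotenone changes had an SD 5.43 times that of the oligomer changes. Shorter RNA on the rotenone arrays stays open, for the dimming and for the calls. Quantile normalization does not remove a change that depends on a probe's place along its transcript. The 3′ minus 5′ difference of the control spots rose by 0.81 (log2, exact p = 0.1, the smallest possible) for GAPDH, where the control SD was 0.153. For PGK1 it rose by 0.129 (exact p = 0.4), where the control SD was 0.194. In control this difference was already 4.67 for GAPDH and 9.02 for PGK1. The 5′ PGK1 spots were dim, at 95.05 in control and 66.08 with rotenone before scaling. Less messenger RNA per rotenone-treated cell, a biological explanation, was not tested, since the labels name no spiked-in RNA that would give an absolute scale. Whether the amount of RNA used differed between the arrays is not stated, so that stays open too.

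Among 68 probes for control spots, those above the control arrays on every array of a treated group and by over 1 (log2) on average, before scaling, were ERCC-00171_229 with oligomers (1.69 higher, signal 30.9 ± 19.3 against 7.73 ± 0.44, SD, n = 3, with 2 of 3 oligomer arrays well above background) and (+)E1A_r60_a107 with rotenone (1.06 higher, 55.7 ± 9.2 against 26.5 ± 1.16, with 3 of 3 rotenone arrays well above background). Both are meant for RNA added by the experimenter, and they were picked from the 68 without a test.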

How the results depend on the processing

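Dim signal limits what can be read here, above all on the rotenone arrays, where 45.1% of probes were well above background, and the direction of some bright genes rests on the scaling. The settings without scaling, with a percentile over probes detected on all 9 arrays, and with scan 1 alone were chosen after seeing the data. So was the median signal for normexp, while normexp itself was planned. The tests of gene lists (camera with a preset or estimated correlation, fry, and other choices of probe) were not run because no list had enough tested genes, and the slide and scan blocks are a single fit. Of the alternatives, 21 of 26 for rotenone against control, 21 of 26 for oligomers against rotenone and 17 of 26 for oligomers against control gave a count within 1.5 times of the main one, and 18 of 23 gave a correlation of the responses within the leave-one-out SD of 0.0625. Where no construction is named, the cause of a difference was not tested.

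For oligomers against control, where the main count was 0, quantile normalization called 1 probe. Normexp called 10 with the percentile and 5 with quantile normalization. No filter on dim probes called 2, and probes well above background on all 9 arrays 5 (with fewer probes to adjust over). An intensity trend with robust spread called 5 and array weights 90. These weights ran from 0.405 for rotenone array 3 to 5.41 for control array 3. An unadjusted p with a 2-fold change gave 123. Leaving out single arrays gave 0 to 46, the 46 without oligomer array 2. For rotenone against control (13996), normexp with the percentile called 22472, no filter 26321 (19075 higher, 7246 lower), no scaling 26498, an adjusted p with a 2-fold change 4539 and an unadjusted p with a 2-fold change 4671, and leaving out single arrays 11134 to 13890. For oligomers against rotenone (14700), the same settings called 22733, 26701 (7372 higher, 19329 lower), 25843, 5076 and 5202, and leaving out single arrays 12484 to 14379. The correlation, −0.0313 in the main setting, was 0.257 with no filter, 0.0379 with the scan as a block, 0.06 with array weights, −0.112 over probes past the threshold in either comparison and from −0.0731 to 0.133 on leaving out single arrays, the 0.133 without control array 2.

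Among genes past the threshold in the main setting or the alternative, signs turned as follows (log2 changes). For rotenone against control, quantile normalization gave ACTB −0.28, GAPDH −0.37, H3-3A −0.18 and RPLP1 −0.19; normexp with quantile normalization gave ACTB −0.27, GAPDH −0.37, H3-3A −0.19 and RPLP1 −0.19; normexp with the percentile gave EIF3D 0.028, GAPDH −0.043 and GRM4 0.21. Without scaling, ACTB was −0.38, ACTG1 −0.81, GAPDH −0.57, H3-3A −0.46, ODC1 −0.081 and RPLP1 −0.20, which the shift of −0.895 that the main scaling takes out accounts for by construction. For oligomers against rotenone, quantile normalization gave ACTB 0.27, GAPDH 0.38, H3-3A 0.18 and RPLP1 0.19; normexp with quantile normalization gave ACTB 0.24, GAPDH 0.37, H3-3A 0.18 and RPLP1 0.19; normexp with the percentile gave ACTG1 −0.22, GAPDH 0.059, GRM4 −0.20, H3-3A 0.022 and PGK1 −0.048. Without scaling, ACTB was 0.37, GAPDH 0.57, H3-3A 0.53, ODC1 0.11, PRMT1 0.051, RPLP1 0.17 and RPS18 0.022. The median change for rotenone against control moved from −0.036 to 0.147 with normexp and the percentile, −0.17 with a median shift and 0.303 with no filter. The offset of 50 used with normexp shrinks log2 changes of dim probes by construction. The named probes without a gene kept their direction in every setting run.

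The arrays share replicate numbers across groups, but same-numbered arrays did not deviate together: the correlations of their deviations ran from −0.328 to 0.174, and 0 of 9 arrays correlated best with their own number. With the replicate block the counts were 0, 12452 and 13203 and the correlation −0.0268; GAPDH (adjusted p = 0.0532), MTX1 (0.0611) and PFN1 (0.0528) then missed the threshold for rotenone against control, as did GAPDH (0.0577) and MTX1 (0.0931) for oligomers against rotenone.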

Other observations

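The tests in this part were chosen after the results were seen. On the oligomer arrays a few dim probes lit up that were near the floor everywhere else. The probe for RACK1, a scaffold protein of the small ribosomal subunit, had signals of 40.0, 15.1 and 45.4 on oligomer arrays 1, 2 and 3, against 3.93 ± 0.473 (SD, n = 3) in control and 3.96 ± 0.394 with rotenone, at least 2.0-fold higher than control with 2 oligomer arrays well above background. The probe for COX4I1, a subunit of cytochrome c oxidase, had 19.5, 10.5 and 18.9 against 5.85 ± 0.493 and 5.77 ± 0.846, without being well above background on any array. Neither was bright enough on 3 arrays to be tested, and both were singled out after their values were seen. The control spot ERCC-00171_229, which matches no human gene by design, had 38.4, 8.95 and 45.3 against 7.73 ± 0.44 in control, with array 2 lowest here too.

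For 4 further probes, all without a gene name here, the 3 oligomer arrays were each over 1 (log2) above all 6 other arrays with at least 2 oligomer arrays well above background. Chance stays open: of the 84 ways to pick 3 of the 9 arrays, the highest that mixed groups also reached 4, while the rotenone arrays gave 1189 and the control arrays 0. Over these probes the 2 oligomer arrays of scan 1 lay 3.13 (log2) above the controls of the same scan. This does not test the scan, since the way the probes were picked puts the value over 1 beforehand. Both scans held oligomer and rotenone arrays, so a difference between the scans alone would not give probes of this pattern. A candidate explanation is nucleic acid added with the oligomer preparation, which could light up probes for sequences that are not human; 1 of 64 such control probes, ERCC-00171_229, was over 1 (log2) higher on average than in both other groups, too few to decide. No biological explanation was tested.

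The rotenone loss of brightness was uneven. Before scaling, the median change of tested probes lay between −1.10 and −0.84 in the lower 9 deciles of brightness and at −0.59 in the brightest decile, where the SD of the changes was 1.06 for rotenone and 0.181 for oligomers. The first principal component held 64.7% of the variance, with rotenone arrays at 88.2 to 102.7, control array 2 at −32.2 and the other 5 arrays between −54.4 and −44.1. The second held 9.14% and set the arrays of scan 2 apart. Oligomer array 1 lay at 27.1 and rotenone array 3 at 54.1, and the arrays of scan 1 between −35.5 and 1.96.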
